A study of Mus musculus with 37 samples.

How the data were processed

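The data are 37 2-colour Agilent mouse arrays from 19 mice, with cartilage of the DMM leg in one channel and of the sham leg of the same mouse in the other. Per the labels' protocols, knees were decalcified and sectioned, tibial cartilage was laser-microdissected, and up to 10 ng of total RNA was amplified in 2 rounds. Microdissection is the step that should remove marrow, bone, synovium and muscle, and amplification in 2 rounds can add variation between legs that arrays of the same RNA share. Each mouse had an array with DMM in Cy5 and a dye swap, except 1 Adamts5Dcat mouse at 1 week with 1 array. Per the labels, 1 WT 1-week sample and 1 Adamts5Dcat dye swap had been removed by the authors for technical reasons.

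The deposited scanner files hold, per the file headers, spot intensity read with Agilent Feature Extraction 9.5.3.1: mean and background signals, processed signals and flags for 45018 spots, of which 43379 are not controls. They also hold the log10 ratio of Cy5 over Cy3 that the software computed, per the file headers, used here only to read the direction and scale of the value table. The authors' deposited value table holds log2 ratios whose normalization is not given in the sources used here; set against each array's own ratios, its columns are on a log2 scale, turned to DMM over sham and centred near 0 (medians from -0.0338 to 0.0147). For 35 of 37 arrays the column matched its own array with r over 0.999. The centring step stays unknown. Coordinates are those of the array design, build mm7 per the file headers. A channel had 23.3% to 79.9% of its spots well above background, median signals from 108 to 1128 and median backgrounds from 47 to 123.

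Background was corrected with normexp (offset 50) on the mean and background signals and ratios were normalized by loess within each array, with control spots at weight 0. Spots that the software marked as non-uniform or population outliers were left out. Dye swaps were turned in sign, and the arrays of a mouse were averaged, so that n counts mice. A probe was kept where at least 3 mice had it well above background in all arrays of the mouse in either leg, which left 31253 of 41174 probes. The brightest probe stood for each of 21774 gene names; 6686 names had several kept probes, and of the 154 with a called probe in WT mice at 2 weeks, 0 had called probes of both signs. An array accession found in the reference table (assembly GRCm38.p6) named 22951 probes, an older or equal symbol named 9768, and 8455 kept the array's name; 4257 tested names were updated.

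limma 3.58.1 in R 4.3.3, with the packages statmod 1.5.0 and data.table (version 1.17.8), fitted 5 group means over the 19 mice (lmFit and eBayes), with Benjamini-Hochberg adjusted p under 0.05 as the threshold, two-sided. Differences between times within a genotype and between genotypes within a time were contrasts of these means. Sham levels were compared between genotypes after Aquantile normalization between arrays. Where a probe was not well above background on any array of a group in one leg, or, in the WT shams, on only 1 or 2 of 8 channels, the fold is a bound: the bright mean against the mean of, per array, the higher of the lowest signal among probes above background and the probe's own. Gene lists were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, over 30 gene lists and 21711 gene names without missing values, which left 4 lists with 1 member fewer than was measured.

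The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule takes, for each DMM comparison, up to 10 genes each way with the largest change among those past the threshold with the same sign in every mouse, leaving out clone and accession identifiers. Where fewer than 10 qualify it takes the 10 smallest p, for differences up to 5 each way, and up to 4 members per list discussed. A panel of cartilage and osteoarthritis genes could also be named in any comparison. Added after the data were seen were the exchanged arrays, fits within each scan batch, fits with means of other tissues as covariates, scan batch as a block in the sham and list tests, the mean of the 5 groups, list tests on time differences and the level of sham probes in the DMM leg.

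Arrays came from 13 slides and were scanned in 2 batches, of 10 mice with 20 arrays and 9 mice with 17 arrays; each group has mice in both. In WT mice at 1 and 6 weeks, same-numbered mice deviated together from their group means with r from 0.146 to 0.256 in each of 3 pairs, which was taken as pairing from the data; the labels say nothing of shared litters, and the replicate numbers follow the scan batch. The block changed no call of this comparison. Alternatives were the processed signals, no background correction, median centring, no filter on dim probes, the mean of a gene's probes, only the groups compared, every array with the mouse as a random block (consensus correlation 0.836), arrays with DMM in Cy5 only, array weights, the value table, trended and robust eBayes, a 2-fold minimum, and each mouse left out. Of 200 simulated changes, the fit recovered 82.1% of those at 4-fold in WT at 2 weeks and 70.1% at 1 week. Power may be lower: Inhba and Fn1, up over 8-fold there, did not pass.

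Replicates are separate mice by the labels. The number of mice limits the precision. Results of 2 genes that the rule takes are not reported here, though these genes stayed in all tests and list counts. No genome of build mm7 was used, so exons were not assigned.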

Results

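Cartilage gene expression was measured on 2-colour Agilent mouse arrays in 19 mice with surgically induced osteoarthritis. In destabilisation of the medial meniscus (DMM) the ligament that ties the medial meniscus to the tibia is cut, and osteoarthritis follows. The right knee had this operation and the left knee was opened and closed as a sham. Cartilage of the tibia was laser-microdissected from sections, which should leave out other tissues, and its RNA was amplified in 2 rounds. Each array set the DMM leg against the sham leg of the same mouse, so every mouse was its own control. Wild-type (WT) mice were taken at 1 week (3 mice, 6 arrays), 2 weeks (4 mice, 8 arrays) and 6 weeks (4 mice, 8 arrays). Mice without catalytically active ADAMTS5, an enzyme that cleaves the cartilage proteoglycan aggrecan, are called Adamts5Dcat and were taken at 1 week (4 mice, 7 arrays) and 6 weeks (4 mice, 8 arrays). The stated question was which genes mark early and late disease and which respond downstream of aggrecan loss. Between 23.3% and 79.9% of the spots of a channel were well above background, and the number of mice, 3 or 4 in a group, limits the precision. Values are log2(DMM/sham), given as mean ± SD over the mice of a group, with limma's adjusted p over 21774 gene names.

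Across genes, the ratios of different mice correlated with r between -0.41 and 0.63, with a mean of 0.20 for mice of the same group and 0.21 for mice of different groups. Without Adamts5Dcat 6-week replicate 4 the range was -0.24 to 0.63 and both means 0.26. That mouse ran against the rest, with r from -0.27 to -0.22 to the other mice of its group. In the value table the columns of its 2 arrays matched the other array of the pair (absolute r 0.99995 and above). The other 35 columns matched their own (r at least 0.99917). This and the slides point to exchanged files, but the direction of this mouse is not settled. It stands as recorded, and results it bears on are also given with arrays exchanged or without it. WT 6-week replicate 4 had a mean r of -0.02 with all other mice and a dye-swap r of 0.956.

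**Figure D1:**
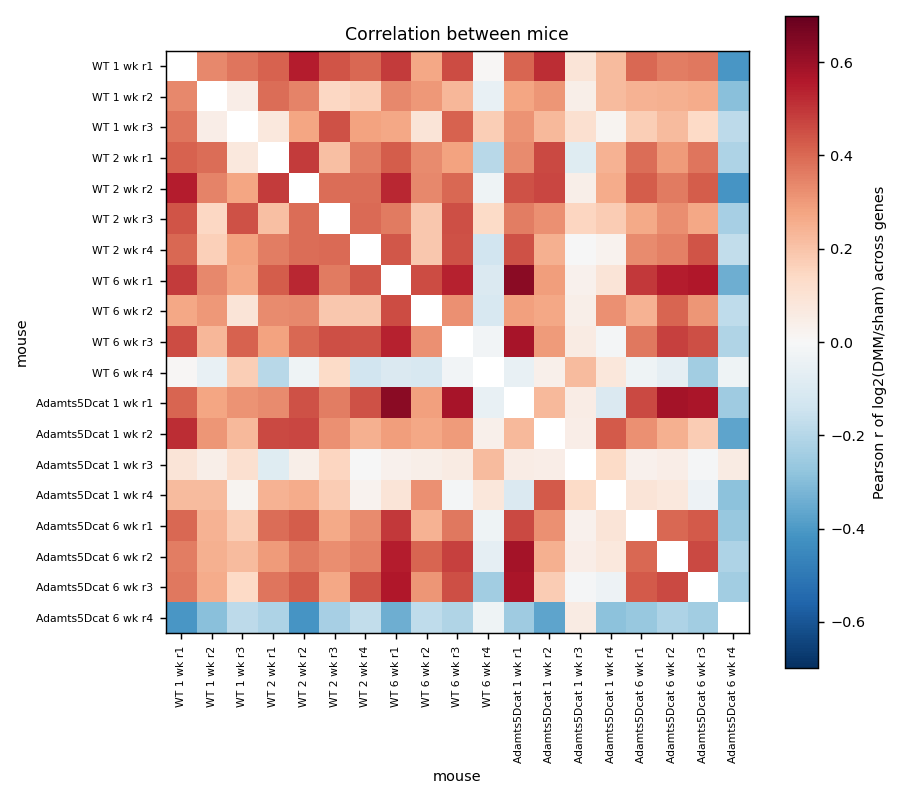
Pearson correlation of log2(DMM/sham) across genes between each pair of the 19 mice, files as recorded, with blue for negative and red for positive r. The row of Adamts5Dcat 6-week replicate 4 is mostly blue, with a mean r of -0.24 to its own group.

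The gene altered in the Adamts5Dcat mice, Adamts5, was measured by a probe on chromosome 16 at 85858359 to 85858419 of build mm7. In sham cartilage its log2 level was 10.5 ± 0.45, 9.86 ± 0.92 and 11.1 ± 0.63 in WT mice at 1, 2 and 6 weeks (n = 3, 4 and 4) and 10.4 ± 0.58 and 11.1 ± 0.41 in Adamts5Dcat mice at 1 and 6 weeks (n = 4 each). Whether this probe lies in the deleted part was not settled here, so these levels check nothing about the genotype. Its log2(DMM/sham) was 0.11 ± 0.94, 1.19 ± 0.82 and -0.25 ± 1.12 in WT mice at 1, 2 and 6 weeks and -0.32 ± 1.19 and 0.0046 ± 0.66 in Adamts5Dcat mice at 1 and 6 weeks, with limma adjusted p from 0.157 to 0.998. The sign turned in 4 of these groups when 1 mouse was left out: 0.22 without WT 6-week replicate 4, -0.39 without WT 1-week replicate 3, 0.20 without Adamts5Dcat 1-week replicate 3, and -0.094 and -0.24 without Adamts5Dcat 6-week replicates 2 and 4.

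At 1 week in WT mice, DMM cartilage had higher RNA of Phlda2, an imprinted gene of the pleckstrin homology family (4.84 ± 1.5, 28.5-fold, n = 3), and of Klk8, a secreted serine protease (3.86 ± 0.68, 14.5-fold). Defb11, a beta-defensin (2.57 ± 0.67), and F5, coagulation factor V (1.90 ± 0.87), rose as well. The adjusted p of these 4 genes lay between 0.0284 and 0.0410, and each was higher in 3 of 3 mice. The remaining gene that passed was AK048147, an identifier named after its value was seen (2.17 ± 0.38, adjusted p = 0.041). In all, 5 genes rose and 0 fell. Genes with the next smallest p did not pass, among them Nfkbiz, an inhibitor of NF-kappaB (2.15 ± 0.43, adjusted p = 0.0506), Col6a3, a chain of type VI collagen (2.52 ± 0.84, 0.0599), and Glul, glutamine synthetase (-1.87 ± 0.54, 0.0757).

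Of the gene groups fixed in advance, TGF-beta and activin genes were shifted up as a set at 1 week in WT mice (32 members, mean 0.72, camera adjusted p = 0.000289), with 0 members past the threshold over all genes and 5 up adjusted over the list alone. This call and those of the 8 other lists called at 1 week were lost with an estimated correlation (adjusted p from 0.729 to 0.786). Immediate early and heat shock genes (0.66, 0.00057; 6 up and 1 down adjusted over the list alone) and collagens and fibrous matrix genes (0.43, 0.00158; 8 up and 1 down adjusted over the list alone) were shifted in the same direction. Examples were Inhba (3.44 ± 0.90), Fosl1 (2.23 ± 0.42) and Fn1 (3.19 ± 0.35), none of which passed over all genes. Hypoxia and glycolysis genes (0.35), oxidative phosphorylation (OXPHOS) genes (0.27) and ribosomal protein genes (-0.23) were shifted with camera adjusted p from 0.0304 to 0.0378, and lost likewise (adjusted p up to 0.786 with an estimated correlation). Of these, 1 hypoxia gene was up adjusted over the list alone. Markers of other tissues moved with this group: neutrophil markers had a mean of -1.14, macrophage markers -0.66 and muscle markers 1.09 (adjusted p up to 0.786 with an estimated correlation). These means were 0.021, 0.12 and 0.044 in the 2 mice of scan batch 1 and -3.47, -2.21 and 3.19 in scan batch 2, which holds only WT 1-week replicate 3. In those batches the TGF-beta mean was 0.67 and 0.83, the immediate early mean 0.44 and 1.11, the collagen mean 0.18 and 0.93 and the hypoxia mean -0.081 and 1.23. Oxidative phosphorylation and ribosomal protein lists were not called with scan batch as a block (camera adjusted p = 0.0547 and 0.0626). Means without 1 mouse of the group stand in parentheses. Without replicate 1, muscle (1.70) kept the call. Without replicate 2, OXPHOS (0.27) lost the call and hypoxia (0.71), macrophage (-1.11) and neutrophil (-1.86) kept it. Without replicate 3, collagens (0.18), ribosomal (-0.052), hypoxia (-0.081), macrophage (0.12), muscle (0.044), neutrophil (0.021) and OXPHOS (0.17) lost the call and immediate early (0.44) kept it. Ribosomal also lost it without WT 6-week replicate 2 (camera adjusted p = 0.05002). With median centring hypoxia (0.25, camera adjusted p = 0.468) and OXPHOS (0.17, 0.673) lost it.

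The count of 5 genes (2899 at an unadjusted p under 0.05) became 1 with scan batch as a block, 8 within batch 1 and 0 within batch 2. Without WT 1-week replicate 1 it was 0, without replicate 2 it was 3, without replicate 3 it was 2, and without the mouse of unsettled direction it was 38. Leaving out 1 mouse of another group gave 0 to 8 genes. It was also 0 in fits of only the groups compared, with trended and robust eBayes, and with the erythroid, neutrophil and muscle list means as covariates (median absolute log2 ratio 2.52 against 2.57, median SE 0.424 against 0.352, 5 of 5 signs kept).

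At 2 weeks in WT mice, 156 genes rose and 146 fell in DMM cartilage (69 and 9 with median centring). The largest rises were in Ptgs2, cyclooxygenase-2 (4.92 ± 1.15, 30.2-fold, n = 4, adjusted p = 0.0306), Il11, a cytokine of the interleukin-6 family (4.65 ± 0.80, 25.1-fold), Mmp3, the metalloproteinase stromelysin-1 (4.41 ± 2.13, 21.3-fold), and Fos, a subunit of the AP-1 transcription factor (4.13 ± 0.98, 17.5-fold). Nt5e, which makes adenosine outside the cell (4.00 ± 0.90), Blm (3.85 ± 0.40), the hyaluronan synthase Has1 (3.82 ± 1.04), Phlda2 (3.79 ± 0.67) and Inhba, the activin A subunit (3.74 ± 0.70, 13.4-fold, adjusted p = 0.0233), followed. The largest falls were in Padi2, a peptidylarginine deiminase (-3.79 ± 0.47, 13.9-fold lower, adjusted p = 0.0271), and Chrdl2, a chordin-like BMP antagonist (-3.61 ± 0.83, 12.2-fold lower, adjusted p = 0.0233). Adamts18 (-3.35 ± 1.04), Selenbp1 (-3.31 ± 1.20), Selenbp2 (-3.25 ± 1.07), Rarres2, the adipokine chemerin (-3.24 ± 0.29), Crispld1 (-3.13 ± 0.84), Zfp503 (-3.02 ± 1.43), Necab3 (-2.91 ± 0.63) and Plxdc1 (-2.86 ± 1.84) fell too. These 19 genes had the same sign in 4 of 4 mice, with adjusted p from 0.0233 to 0.0489. The probe of Ptgs2 lies on chromosome 1 at 150033228 to 150033287, that of Mmp3 on chromosome 9 at 7453874 to 7453933 and that of Inhba on chromosome 13 at 15394279 to 15394338 of build mm7.

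**Figure D2:**
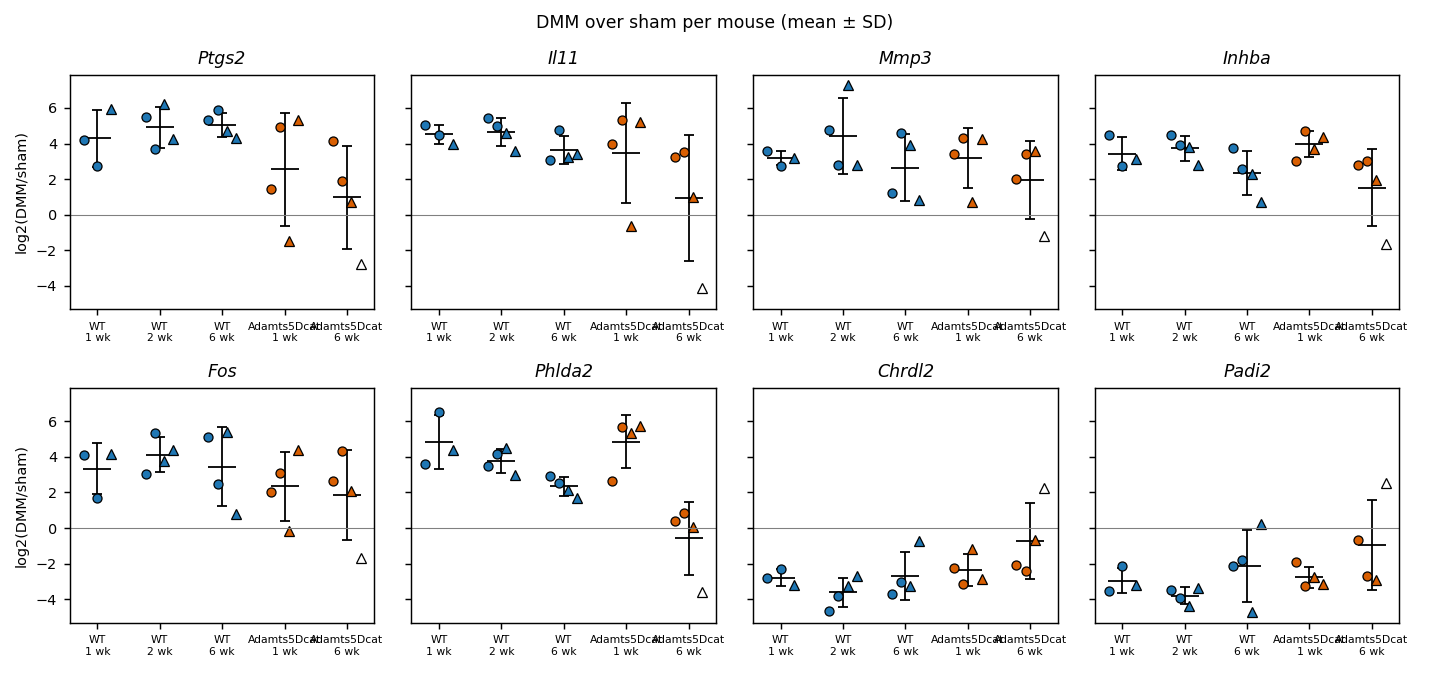
log2(DMM/sham) of 8 genes in each mouse by group, with the horizontal bar at the mean and the error bar at ± SD; blue is WT, orange Adamts5Dcat, circles scan batch 1, triangles scan batch 2, and the open symbol Adamts5Dcat 6-week replicate 4 as recorded. The genes were picked after their values were seen; Ptgs2 had a mean of 4.92 in WT mice at 2 weeks and 5.05 at 6 weeks.

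Among immediate early and heat shock genes at 2 weeks, 5 of 36 rose and 0 fell (15 and 0 adjusted over the list alone), including Fos, Sgk1 (2.67 ± 0.74), Ier3 (2.57 ± 0.63) and Fosl1 (2.44 ± 0.73), and the list mean was 1.06 (camera adjusted p = 3.49e-10, fry adjusted p = 0.0336, and adjusted p = 0.302 with an estimated correlation). Of 32 TGF-beta and activin genes, 4 rose and 1 fell (11 and 2 adjusted over the list alone), with Inhba, Tsc22d1 (2.75 ± 0.57) and the inhibitory Smad7 (2.39 ± 0.54) higher and Nrep (-2.16 ± 1.17) lower (mean 0.81, camera adjusted p = 0.000371, and adjusted p = 0.302 with an estimated correlation). Of 36 inflammatory and NF-kappaB genes, Ptgs2 and Il11 rose and 0 fell (9 up and 1 down adjusted over the list alone; mean 0.67, camera adjusted p = 0.0156, and adjusted p = 0.302 with an estimated correlation). Of 59 collagens and fibrous matrix genes, 2 rose and 2 fell, among them Col6a3 (1.63 ± 0.26) higher and Col8a2 (-2.81 ± 0.72) and Col16a1 (-2.53 ± 0.51) lower (12 up and 4 down adjusted over the list alone; mean 0.43, camera adjusted p = 0.0123, and adjusted p = 0.501 with an estimated correlation). Of 44 matrix-degrading proteases, Mmp3 and Plat, the tissue plasminogen activator (3.08 ± 1.04), rose and Adamts18 fell (3 up and 2 down adjusted over the list alone; mean 0.35, camera adjusted p = 0.0485, and 0.0574 with the arrays of 1 mouse exchanged). With an estimated correlation the protease call was lost (adjusted p = 0.302). Means without 1 mouse follow. Without replicate 1, collagens (0.34), inflammatory (0.53) and proteases (0.25) lost the call. Without replicate 2, proteases (0.41) lost the call. Proteases also lost it without Adamts5Dcat 1-week replicates 1 and 4, Adamts5Dcat 6-week replicates 1, 3 and 4 and WT 6-week replicates 1 and 2 (camera adjusted p up to 0.0606). Proteases lost it with median centring (0.58, camera adjusted p = 0.0899), processed signals (0.45, camera adjusted p = 0.0642) and no background correction (0.35, camera adjusted p = 0.0557).

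Cartilage matrix genes were not shifted as a set at 2 weeks (mean -0.20, camera adjusted p = 0.257; 1 of 37 up and 2 down, 3 and 6 adjusted over the list alone). Col2a1, the main cartilage collagen, fell (-1.27 ± 0.48, adjusted p = 0.0407) and Chst11, which sulphates chondroitin, rose (1.17 ± 0.77). Prxl2b, which fell (-1.18 ± 0.19), entered this list through an old clone symbol and is not a matrix gene. Acan, the aggrecan core protein (0.65 ± 0.44), Sox9 (0.97 ± 0.76), Comp (-1.94 ± 0.43), Col10a1 (2.60 ± 1.33), Fn1 (2.55 ± 0.35), Mmp13 (0.23 ± 1.91), Mmp2 (0.83 ± 1.78), Timp1 (1.70 ± 1.18) and Tnfaip6 (3.51 ± 1.74) did not pass. The mean of Mmp13 was -0.38 without WT 2-week replicate 1 and -0.055 without replicate 2, and that of Mmp2 was -0.052 without replicate 1. Of 32 BMP genes, Id2 (3.19 ± 0.98) and Bmp2 (2.49 ± 1.34) rose while Chrdl2 and Rgma (-1.39 ± 0.41) fell (7 and 6 adjusted over the list alone). Of 43 growth factor and nerve-related genes, Hbegf (3.05 ± 0.92), Fgf1 (2.82 ± 0.69) and Errfi1 (2.42 ± 0.32) rose and 0 fell (5 and 2 adjusted over the list alone), although the median of the list was -0.00016 against a mean of 0.41. Of 33 adhesion receptors Has1 and the hyaluronan receptor Cd44 (2.26 ± 0.44) rose (4 and 0 adjusted over the list alone). Of 33 hypertrophy genes, Ank, a pyrophosphate transporter (2.92 ± 1.00), and Atf4 (1.28 ± 0.21) rose (3 up and 3 down adjusted over the list alone). Of 36 genes of endoplasmic reticulum folding and secretion without missing values, of 37 measured, Atf4 rose and Serpinh1 (-1.23 ± 0.79) and Crtap (-1.03 ± 0.29), which help fold collagen, fell (3 and 4 adjusted over the list alone). Of 26 synovial and fibroblast markers, Has1 and Hbegf rose (4 and 3 adjusted over the list alone). The mean of that list, 0.36 (camera adjusted p = 0.332, median 0.072; 0.45 and 0.28 within scan batches 1 and 2), was above 0 in 4 of 4 mice.

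Ribosomal protein genes at 2 weeks had a mean of -0.30, or 0.017 with median centring (camera adjusted p = 0.0123, 0.837 as adjusted p with an estimated correlation), of which Rpl37 fell (-1.04 ± 0.81), with 0 up and 2 down adjusted over the list alone. Oxidative stress genes had a mean of 0.30 (camera adjusted p = 0.0467, and adjusted p = 0.642 with an estimated correlation), although the member that passed, Gstm1, fell (-1.51 ± 0.22), with 4 up and 1 down adjusted over the list alone. Neutrophil markers had a mean of 0.82 and muscle markers -1.20 (camera adjusted p = 0.0473 and 0.000117, and adjusted p = 0.837 and 0.642 with an estimated correlation). No member of these 2 lists passed over all genes or adjusted over the list alone, and the neutrophil list had a camera adjusted p of 0.0574 with the arrays of 1 mouse exchanged. Macrophage and leukocyte markers were not called (mean 0.57, camera adjusted p = 0.0604; 1.16 and -0.015 within scan batches 1 and 2). Within scan batches 1 and 2 the muscle means were 0.0065 and -2.41, the neutrophil means 1.21 and 0.44 and the immediate early means 1.08 and 1.04. The TGF-beta means were 0.78 and 0.83, the inflammatory means 0.82 and 0.53, and those of the collagens 0.41 and 0.46. The proteases had 0.43 and 0.27, the oxidative stress genes 0.22 and 0.39 and the ribosomal protein genes -0.30 and -0.30. All of the lists called at 2 weeks stayed called with scan batch as a block. Means without 1 mouse follow. Without replicate 1, ribosomal (-0.27), neutrophil (0.43) and oxidative stress (0.31) lost the call. Without replicate 3, neutrophil (1.48) kept the call. Without replicate 4, muscle (-0.26), neutrophil (0.42) and oxidative stress (0.24) lost the call. Neutrophil also lost it without Adamts5Dcat 1-week replicates 1, 3 and 4 and Adamts5Dcat 6-week replicate 4 (camera adjusted p up to 0.0606). Oxidative stress also lost it without Adamts5Dcat 1-week replicate 3 (camera adjusted p = 0.0505). With median centring ribosomal (0.017, camera adjusted p = 0.221) and neutrophil (1.07, 0.0899) lost it.

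The 302 genes (4382 at an unadjusted p under 0.05) became 317 with scan batch as a block, 50 within batch 1 and 0 within batch 2. Leaving out any 1 of the 4 WT 2-week mice left 0 genes, and so did a prior that follows intensity with robust variances or the erythroid, neutrophil and muscle list means as covariates (median absolute log2 ratio 1.58 against 1.63, median SE 0.404 against 0.347, 302 of 302 signs kept). Leaving out the mouse of unsettled direction gave 857 and exchanging its arrays 946, of which 298 were among the 302.

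**Figure D3:**
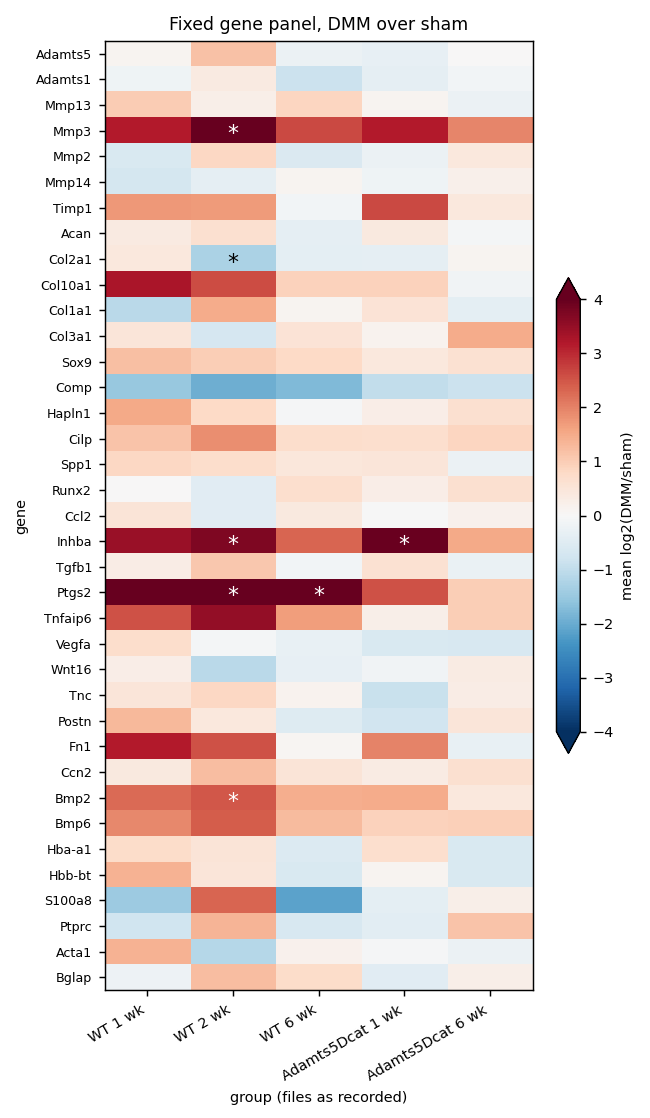
Mean log2(DMM/sham) of the 37 measured genes of a fixed panel, in the 5 groups with files as recorded. Red is higher in DMM, values beyond 4 on either side take the darkest colour, and asterisks mark an adjusted p under 0.05, which 7 of the 185 gene and group pairs reached.

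At 6 weeks in WT mice, 65 genes rose and 51 fell (59 and 4 with median centring). Ptgs2 was again higher (5.05 ± 0.69, 33.2-fold, n = 4, adjusted p = 0.0379), as was Pla2g4a, the cytosolic phospholipase A2 that frees arachidonic acid (2.22 ± 1.11). Npr3, the natriuretic peptide clearance receptor (3.21 ± 1.44), Tal2 (3.04 ± 1.06), Gna14 (2.99 ± 0.94), Atp6ap2 (2.79 ± 1.11), Dyrk3 (2.64 ± 0.83), Chn2 (2.37 ± 1.47), the oxygen-sensing Hif1a (2.27 ± 0.37) and Twist2 (2.21 ± 0.61) rose too. The largest falls were in the transcription factor Sox8 (-2.42 ± 1.16, 5.36-fold lower), the imprinted non-coding RNA Meg3 (-2.26 ± 1.10), Rasgef1a (-2.23 ± 1.27), the monoacylglycerol lipase Mgll (-2.16 ± 0.87), Phka2 (-1.93 ± 0.67), Amhr2 (-1.80 ± 1.14), Nol3 (-1.73 ± 0.89), Dock6 (-1.71 ± 1.00), Prkcz (-1.70 ± 1.25) and Mapk8ip3 (-1.69 ± 0.59). These 20 genes had the same sign in 4 of 4 mice, with adjusted p from 0.0312 to 0.0480.

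Immediate early and heat shock genes were shifted up as a set at 6 weeks (mean 0.63, camera adjusted p = 0.000212; 0 of 36 passed over all genes, 7 up and 1 down adjusted over the list alone), as were TGF-beta genes (0.49, 0.0123; 0 of 32 passed, 1 up and 0 down adjusted over the list alone) and oxidative phosphorylation genes (0.31, 0.0123; 0 of 38 passed, 1 up and 0 down adjusted over the list alone). These 3 calls were lost with an estimated correlation (adjusted p = 0.9). Cell cycle genes had a mean of -0.60 (0.00902; 0 of 41 without missing values, of 42 measured, passed, 0 up and 1 down adjusted over the list alone), lost likewise (adjusted p = 0.9 with an estimated correlation). Of 36 inflammatory genes Ptgs2 rose and Nfkbia, the NF-kappaB inhibitor, fell (-1.01 ± 0.27), with 4 up and 1 down adjusted over the list alone; the list mean was 0.23 and its median -0.046. Of 37 cartilage matrix genes Chst11 rose (1.27 ± 0.21) and Prxl2b fell (-1.31 ± 0.76), with 2 up and 5 down adjusted over the list alone. Erythroid markers had a mean of -0.67 and neutrophil markers -1.22 (camera adjusted p = 0.0158 and 0.00554; adjusted p = 0.9 with an estimated correlation). Macrophage markers (-0.41, camera adjusted p = 0.133; 0.62 and -1.44 within scan batches 1 and 2) and synovial and fibroblast markers (0.37, camera adjusted p = 0.137) were not called. Within scan batches 1 and 2 the erythroid means were 0.44 and -1.77, the neutrophil means 0.19 and -2.64 and the cell cycle means 0.22 and -1.36. The immediate early means were 0.70 and 0.56, the TGF-beta means 0.43 and 0.55 and the oxidative phosphorylation means 0.18 and 0.43. All of the lists called at 6 weeks stayed called with the batch as a block. Means without 1 mouse follow. Without replicate 1, erythroid (-1.03) kept the call. Without replicate 2, erythroid (-1.04) kept the call. Without replicate 3, TGF-beta (0.38), cell cycle (-0.46), erythroid (-0.28) and OXPHOS (0.16) lost the call. Without replicate 4, TGF-beta (0.56), cell cycle (-0.19), erythroid (-0.31) and neutrophil (-0.63) lost the call.

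The 116 genes (3897 at an unadjusted p under 0.05) became 154 with scan batch as a block, 615 within batch 1 and 0 within batch 2. Without WT 6-week replicate 1 the count was 1, without replicate 2 or 3 it was 0 and without replicate 4 it was 1823. Without the mouse of unsettled direction it was 713, and with its arrays exchanged 817, which include the 116; leaving out 1 mouse of the other groups gave between 41 and 187 where it moved the count by over 1.5 times. It was 0 in fits of only the groups compared and with trended and robust eBayes, and 1 with the covariates for other tissues (median absolute log2 ratio 1.44 against 1.45, median SE 0.323 against 0.292, 116 of 116 signs kept).

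In Adamts5Dcat mice at 1 week, Phlda2 (4.86 ± 1.47, 29-fold, n = 4, adjusted p = 0.0134), Inhba (3.95 ± 0.73, 15.5-fold, 0.0293) and Prkg2, a cGMP-dependent protein kinase that drives chondrocyte differentiation (3.26 ± 1.37, 0.0293), rose in 4 of 4 mice. Arvcf, a catenin-family protein of cell junctions, fell in 4 of 4 (-1.86 ± 0.56, 0.0293). These 3 up and 1 down were all the genes that passed, against 1713 at an unadjusted p under 0.05. Moxd1 (2.86 ± 0.59), Hmga1 (2.73 ± 1.41), Defb11 (1.70 ± 0.73), Evi2a (2.90 ± 1.13), Rnf125 (1.61 ± 0.55) and the TNF receptor Tnfrsf1a (1.16 ± 0.35) came next and did not pass, with adjusted p from 0.0975 to 0.135. Hypoxia and glycolysis genes were shifted down as a set (-0.52, camera adjusted p = 4.52e-05, and adjusted p = 0.934 with an estimated correlation), with the carbonic anhydrase Car9 at -2.21 ± 1.22. Oxidative phosphorylation genes (0.30, 4.52e-05), ribosomal protein genes (0.28, 4.52e-05), oxidative stress genes (0.29, 0.0382) and immediate early genes (0.36, 0.0137) were shifted up, and lost with an estimated correlation (adjusted p = 0.934). No member of these 5 lists passed over all genes or adjusted over the list alone, except for 1 immediate early gene adjusted over the list alone. Of the TGF-beta genes, Inhba rose and 3 rose adjusted over the list alone; this list had a camera adjusted p of 0.0703, and of 0.0299 with the arrays of 1 mouse exchanged (there adjusted p = 0.828 with an estimated correlation). Macrophage markers moved with this group (mean -0.51, camera adjusted p = 0.01; adjusted p = 0.934 with an estimated correlation). Means without 1 mouse follow. Without replicate 1, immediate early (0.31) and oxidative stress (0.13) lost the call. Without replicate 2, immediate early (0.22) and oxidative stress (0.28) lost the call and ribosomal (0.47) and hypoxia (-0.34) kept it. Without replicate 3, ribosomal (-0.033), macrophage (-0.073) and oxidative stress (0.30) lost the call and immediate early (0.64) kept it. Without replicate 4, immediate early (0.26) lost the call and oxidative stress (0.44) kept it. With median centring oxidative stress (0.18, camera adjusted p = 0.0707) and macrophage (-0.55, 0.106) lost it.

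Within scan batches 1 and 2 of the Adamts5Dcat 1-week mice, the hypoxia means were -0.47 and -0.58, the oxidative phosphorylation means 0.34 and 0.27 and the ribosomal protein means -0.017 and 0.57. The oxidative stress means were 0.54 and 0.032, the immediate early means 0.63 and 0.082 and the macrophage means -0.15 and -0.86. All of these lists stayed called with the batch as a block. The count of 4 genes became 6 with the block, 3 within batch 1 and 0 within batch 2. Without Adamts5Dcat 1-week replicate 1 or 3 it was 1, without replicate 2 or 4 it was 0, without the mouse of unsettled direction it was 24, and with its arrays exchanged 37, which include the 4. Leaving out 1 mouse of another group gave 1 or 2 where it moved the count. It was 0 in fits of only the groups compared, with trended and robust eBayes, and with the covariates for other tissues (median absolute log2 ratio 3.63 against 3.61, median SE 0.59 against 0.545, 4 of 4 signs kept).

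In Adamts5Dcat mice at 6 weeks, limma called 0 genes with the files as recorded, against 2271 at an unadjusted p under 0.05. The smallest p belonged to Mief2, a mitochondrial fission factor (1.02 ± 0.52, adjusted p = 0.341), Eps8, an actin regulator (1.46 ± 0.57, 0.431), Efna2 (1.15 ± 0.50, 0.431) and Rgs7, which was not well above background in DMM cartilage and was at least 1.61-fold lower there; none of these passed. With the arrays of replicate 4 exchanged, 60 genes rose and 91 fell, and without that mouse 13 genes passed. Genes with large changes in the exchanged setting, chosen after their values were seen, were the neuropeptide Npy (4.13 exchanged and 3.94 over 3 mice), Crtac1, a cartilage matrix protein (3.88 exchanged and 3.65 over 3 mice, adjusted p = 0.000101 when exchanged) and Adamts18 (-2.52 exchanged and -2.53 over 3 mice). Protease inhibitors (0.33, camera adjusted p = 0.0418), immediate early genes (0.31, 0.0418) and oxidative phosphorylation genes (0.27, 0.00435) were shifted up as sets as recorded, with 0 members past the threshold over all genes or adjusted over the list alone. All 3 were lost with an estimated correlation (adjusted p = 0.785), and protease inhibitors also with the batch as a block (camera adjusted p = 0.0503). Means without 1 mouse follow. Without replicate 1, immediate early (0.33) lost the call. Without replicate 2, immediate early (0.10) and protease inhibitors (0.16) lost the call and OXPHOS (0.17) kept it. Without replicate 3, protease inhibitors (0.27) lost the call. Without replicate 4, immediate early (0.51), OXPHOS (0.42) and protease inhibitors (0.51) kept the call. Immediate early also lost it without WT 6-week replicate 4 (camera adjusted p = 0.0607). Protease inhibitors also lost it without WT 1-week replicate 2 and WT 6-week replicate 4 (camera adjusted p up to 0.072). The means of these 3 lists were 0.43, 0.46 and 0.37 when exchanged, 0.51, 0.60 and 0.41 in scan batch 1 and 0.15, 0.024 and 0.13 in scan batch 2. TGF-beta genes (0.42, camera adjusted p = 0.0498) and oxidative stress genes (0.34, 0.0117) were called only when exchanged, and not with an estimated correlation (adjusted p = 0.707 and 0.536 when exchanged). Of the markers of other tissues, which were not called as recorded, the endothelial mean was -0.34 (camera adjusted p = 0.138), below 0 in 4 of 4 mice as recorded, and -0.25 when exchanged, below 0 in 3 of 4. Neutrophil means ran from -1.13 to 2.79 (mean 0.42, camera adjusted p = 0.107; -0.60 and 1.45 within scan batches 1 and 2). The count stayed 0 with the block and within either batch.

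**Figure D4:**
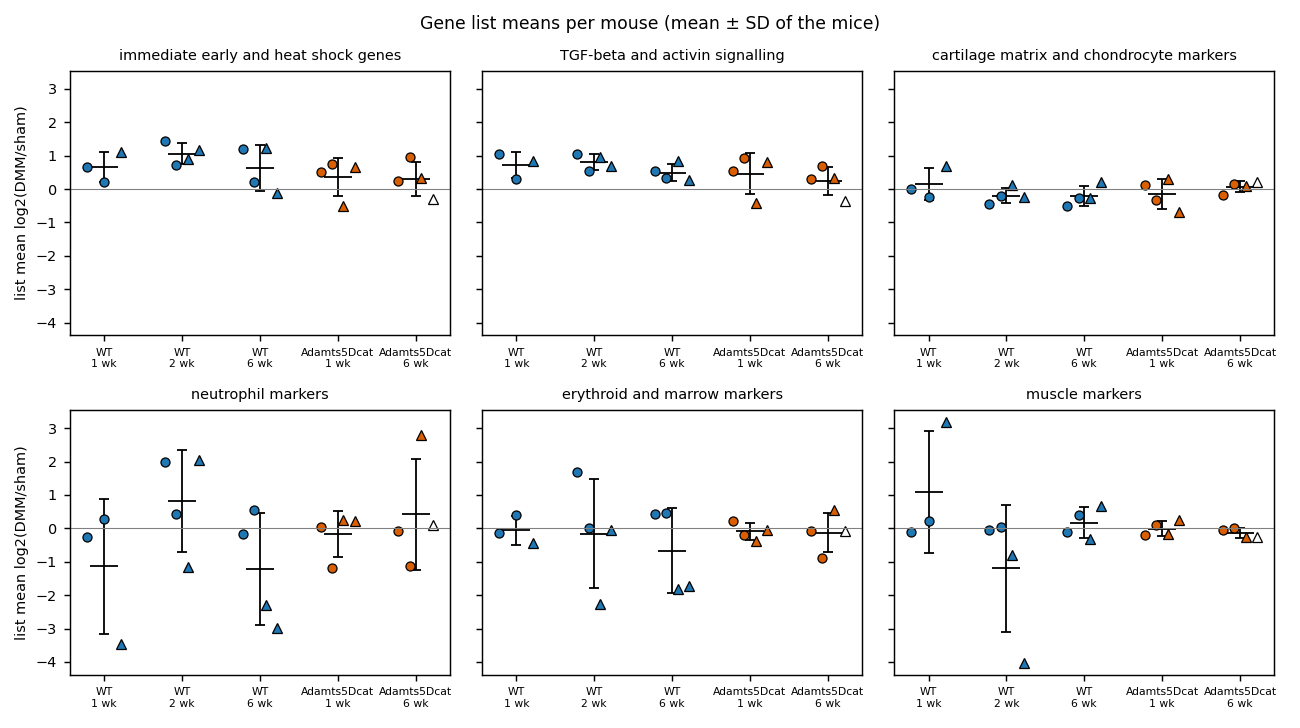
Mean log2(DMM/sham) of 6 gene lists in each mouse by group, with the bar at the mean of the mice and the error bar at ± SD; blue is WT, orange Adamts5Dcat, circles scan batch 1, triangles scan batch 2, and the open symbol Adamts5Dcat 6-week replicate 4 as recorded. Neutrophil means spread from -3.47 to 2.79 and muscle means from -4.02 to 3.19.

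The early and late responses were compared by the difference of log2(DMM/sham) between times. In WT mice, the genes with the smallest p for 2 weeks minus 1 week included Dhrs2 (1.92 (SE 0.42)), the Polycomb subunit Cbx8 (1.57 (SE 0.40)), Col2a1 (-1.68 (SE 0.43)) and the neurofilament Nefl (-1.80 (SE 0.48)). For 6 weeks minus 1 week they included Lrrn3 (2.99 (SE 0.63)), Cbx8 (1.73 (SE 0.40)) and M1ap (-1.97 (SE 0.47)). In Adamts5Dcat mice, Phlda2 had the smallest p for 6 weeks minus 1 week (-5.42 (SE 0.89), adjusted p = 0.268); with the arrays of replicate 4 exchanged its difference was -3.62 (adjusted p = 0.99979). limma called 0 genes in each of these 3 differences, against 767, 905 and 992 at an unadjusted p under 0.05, and every adjusted p of the genes named other than Phlda2 was above 0.99. With the arrays exchanged the counts were 0 as well (844, 990 and 899 at an unadjusted p under 0.05), as with scan batch as a block and within each batch. All of these numbers at an unadjusted p lie below the share of 0.05 of the gene names that chance alone would give. Simulations recovered 50.7%, 53.7% and 52.2% of 4-fold and 77.3%, 75.8% and 77.3% of 8-fold changes, and may overstate power.

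The genotypes were compared by the difference of log2(DMM/sham), Adamts5Dcat minus WT. At 1 week the genes with the smallest p were Xlr3c (-3.53 (SE 0.80)), the DNA repair glycosylase Ogg1 (1.20 (SE 0.30)), P2ry4 (0.87 (SE 0.22)), Trp53bp1 (-0.91 (SE 0.23)) and the linker histone H1f4 (1.99 (SE 0.52)). At 6 weeks they were Prl2b1 (-1.53 (SE 0.32)), Zfp69 (1.55 (SE 0.33)), Mief2 (1.05 (SE 0.24)), Ifrd1 (-1.20 (SE 0.28)) and Slc35f1 (-1.39 (SE 0.33)). None passed (adjusted p = 0.988 at 1 week and 0.995 at 6 weeks): limma called 0 genes at either time, against 786 and 975 at an unadjusted p under 0.05, and 0 with the arrays exchanged (858 and 862), with scan batch as a block or within each batch. Simulations recovered 49.3% and 59.7% of 4-fold and 13.4% and 19.4% of 2-fold changes, and may overstate power.

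In sham cartilage, levels were set across arrays to compare the genotypes in the leg without DMM. At 1 week 1 probe and at 6 weeks 2 probes passed, all higher in Adamts5Dcat mice, against 436 and 549 gene names at an unadjusted p under 0.05; all are unnamed transcripts, picked out here because so few passed. The probe NAP018089-001, which has no coordinate in the files and the sequence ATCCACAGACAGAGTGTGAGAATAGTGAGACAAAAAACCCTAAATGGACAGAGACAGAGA, had a log2 level of 10.1 ± 0.66 in Adamts5Dcat (n = 4) at 1 week and was not well above background in WT mice (n = 3). It was well above background on 7 of 7 Adamts5Dcat and 0 of 6 WT sham channels, and at least 6.1-fold higher (adjusted p = 0.00206). At 6 weeks its levels were 9.94 ± 0.62 and 7.19 ± 0.33 (n = 4 each), at least 6.35-fold higher (adjusted p = 0.00561), with 8 of 8 and 2 of 8 channels above background. The lowest of the 8 Adamts5Dcat shams was at 9.09 and the highest of the 11 WT shams at 7.61. The probe NAP056910-1, on chromosome 4 at 120406569 to 120406628 of build mm7, was at least 5.33-fold higher at 6 weeks (9.76 ± 0.88 against 7.21 ± 0.23, n = 4 each, adjusted p = 0.00778), above background on 8 of 8 and 1 of 8 channels. At 1 week its 4 Adamts5Dcat shams, at 6.94 to 7.07, lay within the range of the 11 WT shams, 6.85 to 7.73. Without WT or Adamts5Dcat 6-week replicate 3 the 6-week count was 1. With scan batch as a block the counts were 1 and 2.

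**Figure D5:**
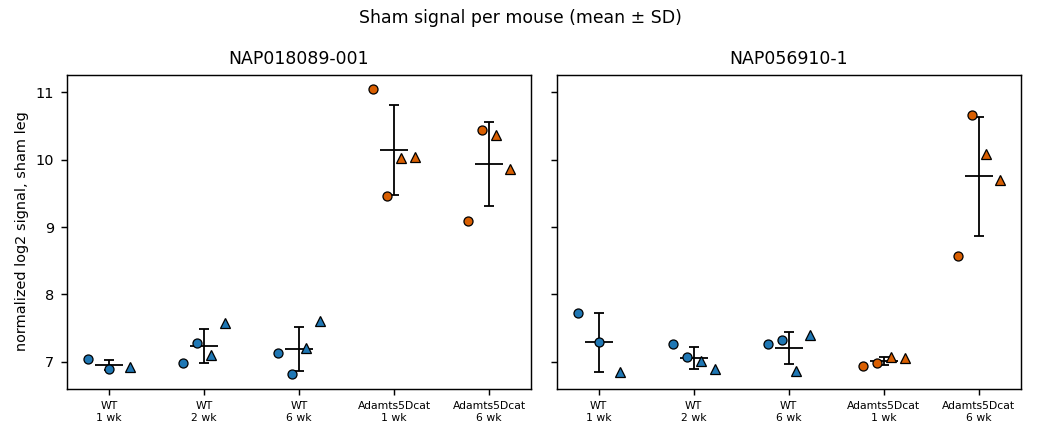
Normalized log2 signal of the sham leg of each mouse for the probes that differed between genotypes, with the bar at the group mean and the error bar at ± SD; blue is WT, orange Adamts5Dcat, circles scan batch 1 and triangles scan batch 2. For NAP018089-001 the lowest of the 8 Adamts5Dcat mice sits at 9.09 and the highest of the 11 WT mice at 7.61.

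Across genes, which are not independent replicates, the mean responses of the 5 groups correlated with Pearson r from 0.29 to 0.60 as recorded and from 0.49 to 0.63 with the arrays of 1 mouse exchanged. The lowest, of WT mice at 1 week with Adamts5Dcat mice at 6 weeks, was 0.29 as recorded, 0.49 exchanged and 0.43 without that mouse. Of the 302 genes called in WT mice at 2 weeks, 97.0% had the same sign in WT mice at 1 week, 95.4% in WT mice at 6 weeks, 97.0% in Adamts5Dcat mice at 1 week and 89.7% in Adamts5Dcat mice at 6 weeks (94.4% without the mouse of unsettled direction). WT mice at 2 and 6 weeks shared 15 genes up and 8 down, against 0.466 and 0.342 for independent lists (134 and 103 against 8.79 and 8.95 with the arrays exchanged). In scan batch 1 r was 0.45 to 0.64 and in batch 2, as recorded, -0.14 to 0.43 (from 0.089 without Adamts5Dcat 6 weeks).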

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

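The tests of explanations in this part were chosen only after the results were seen, as were the list tests on the time differences; the split tests are given further on with their origin.

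The ratios of Adamts5Dcat 6-week replicate 4 opposed those of the other mice of its group, with a mean r of -0.24 that stands far from the other 3. Exchange of the 2 scanner files of its dye pair has the values it needs: in the value table each column of the pair matched the other array with an absolute r of at least 0.99995. Weak or noisy arrays are argued against, since its dye-swap pair correlated at 0.881, above at least 1 other mouse of the group. In the value table its mean r with the other 3 mice was 0.239, but the table may itself have been turned. A truly opposite response is argued against by the slides. Slide 9 otherwise held only arrays with DMM in Cy5 and slide 10 only dye swaps, and this mouse was recorded the other way round. Its direction is still not settled for certain.

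Neutrophil and muscle markers swung between mice, with list means from -3.47 to 2.79 and from -4.02 to 3.19 and both signs in 5 of 5 groups. Group means can still differ, so a time or genotype effect stays open. With batch means removed, neutrophil spread was 2.88 times as wide in batch 2 as in batch 1. This tests no shared shift, so a scan batch effect stays open. Unequal marrow, leukocyte or muscle tissue in the legs of a mouse may account for the swings, a hypothesis, in spite of the microdissection. Neutrophil and erythroid means correlated across the 19 mice (r = 0.707, permutation p = 0.00115, adjusted p = 0.0023; rho = 0.788, p = 0.00014, adjusted p = 0.00028; r = 0.731 without the 2 farthest mice, 0.705 with the arrays exchanged, 0.907 within batch 1 and 0.688 within batch 2). Neutrophil and muscle means, the other of 2 relations tested, had r = -0.573 (permutation p = 0.0143, adjusted p = 0.0143) but rho = -0.204 (p = 0.405), with r = -0.317 without the 2 farthest mice, 0.088 within batch 1 and -0.663 within batch 2, so that r rests on those mice. The most abundant markers had mean sham log2 levels of 15.51 for Hbb-bt, 13.79 for S100a9, 14.63 for Tnni2 and 14.86 for H2-Ab1, and of the 23 neutrophil, 29 erythroid, 26 muscle and 36 macrophage markers 3, 5, 3 and 4 were above background in all shams and 1, 0, 0 and 4 stand in another list.

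For the 302 genes called in WT mice at 2 weeks, a dye effect is argued against, since a share of 0.997 had the same sign in both dye orientations. With erythroid, neutrophil and muscle list means as covariates the median absolute log2 ratio was 1.58 against 1.63 without, 0.973 of it. The sign was kept in 302 of 302. That fit calls 0 of them, because the median SE grew from 0.347 to 0.404 and the residual degrees of freedom fell from 14 to 11. The call itself needs a low spread between mice, so unequal tissue stays open, as do synovium, macrophages and others not in that fit. A difference between right and left legs that needs no surgery cannot be told apart from DMM, since 0 mice had DMM on the left. A response to DMM stays open as a hypothesis beside it.

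Of 228 groups of values tested for 1 far sample, 9 stood out, where chance gives about 1 in 20. Besides the mean r above, these were log2(DMM/sham) of Smad7 (1.59) and Csf3r (-0.0909) in WT 2-week replicate 2, of Sod3 in WT 2-week replicate 3 (1.87) and of Mmp2 in WT 2-week replicate 1 (3.49). In WT mice at 6 weeks they were Pla2g4a in replicate 2 (3.87) and Sox8 (-0.69) and Smad7 (-0.88) in replicate 4, and in Adamts5Dcat mice at 1 week Phlda2 in replicate 1 (2.67).

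Gene lists whose mean response differed between groups by camera with the preset correlation follow, each with the difference of means and, in parentheses, that within scan batches 1 and 2; all were lost with an estimated correlation. For 2 weeks minus 1 week in WT mice these were neutrophil 1.96 (1.19 and 3.90), macrophage 1.23 (1.04 and 2.20) and muscle markers -2.29 (-0.037 and -5.60), cell cycle 0.63 (0.57 and 1.00), immediate early 0.40 (0.63 and -0.066), cartilage matrix -0.36 (-0.22 and -0.77) and oxidative phosphorylation genes -0.26 (-0.033 and -0.59), with camera adjusted p up to 0.00378 and at least 0.464 as adjusted p with an estimated correlation. For 6 weeks minus 1 week in WT mice they were muscle markers -0.92 (0.11 and -3.00), collagens -0.42 (-0.14 and -0.95), hypoxia -0.41 (-0.098 and -1.15) and cartilage matrix genes -0.37 (-0.28 and -0.72) (up to 0.013; adjusted p at least 0.909 with an estimated correlation). For 6 weeks minus 1 week in Adamts5Dcat mice they were macrophage markers 0.73 (0.16 and 1.31), hypoxia 0.63 (0.61 and 0.65), endoplasmic reticulum 0.30 (-0.16 and 0.79) and Wnt genes 0.23 (0.17 and 0.29) (up to 0.0272; adjusted p at least 0.541 with an estimated correlation). Wnt genes were at 0.067 (camera adjusted p = 0.313) with the arrays of 1 mouse exchanged. Differences without 1 mouse (r for replicate) stand in parentheses next, with ER for endoplasmic reticulum, first for 2 weeks minus 1 week. Without WT 1-week r2, immediate early (0.18) lost the call and cartilage (-0.56) kept it. Without WT 1-week r3, cartilage (-0.092), cell cycle (0.27), macrophage (0.45) and OXPHOS (-0.16) lost the call and immediate early (0.62), muscle (-1.25) and neutrophil (0.80) kept it. Without WT 2-week r1, cell cycle (0.35) and immediate early (0.27) lost the call and macrophage (0.80) kept it. Without WT 2-week r3, cell cycle (1.04) kept the call. Without WT 2-week r4, OXPHOS (-0.12) lost the call and muscle (-1.35) kept it. With median centring cartilage (0.022, camera adjusted p = 0.096) and OXPHOS (0.19, 0.781) lost it. These are for WT mice at 6 weeks minus 1 week. Without WT 1-week r1, muscle (-1.53) kept the call. Without WT 1-week r2, cartilage (-0.56) and hypoxia (-0.77) kept the call. Without WT 1-week r3, cartilage (-0.094), collagens (-0.16), hypoxia (0.029) and muscle (0.13) lost the call. Without WT 6-week r2, hypoxia (-0.24) lost the call. With median centring cartilage (0.25, camera adjusted p = 0.654), collagens (0.044, 0.0664) and hypoxia (0.31, 0.904), and with processed signals hypoxia (-0.38, camera adjusted p = 0.107) lost it. The last are for Adamts5Dcat mice. Without Adamts5Dcat 1-week r1, ER (0.62) kept the call. Without Adamts5Dcat 1-week r3, Wnt (0.19), ER (0.15) and macrophage (0.30) lost the call. Without Adamts5Dcat 1-week r4, ER (0.13) lost the call. Without Adamts5Dcat 6-week r2, Wnt (0.18) and ER (0.16) lost the call. Without Adamts5Dcat 6-week r3, ER (0.20) and macrophage (0.52) lost the call. Without Adamts5Dcat 6-week r4, Wnt (0.13) lost the call. With median centring Wnt (0.58, camera adjusted p = 0.24) and macrophage (0.85, 0.493), and with processed signals Wnt (0.29, camera adjusted p = 0.0762) lost it.

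For Adamts5Dcat minus WT at 1 week the lists were neutrophil 0.98 (-0.59 and 3.71) and muscle markers -1.10 (-0.092 and -3.16), hypoxia -0.88 (-0.39 and -1.80), cell cycle 0.57 (-0.11 and 1.57), ribosomal protein 0.51 (0.035 and 1.16), collagen -0.47 (0.066 and -1.25), cartilage matrix -0.30 (0.020 and -0.90) and TGF-beta genes -0.26 (0.065 and -0.64), again with the difference within scan batches 1 and 2 in parentheses (camera adjusted p up to 0.0397; adjusted p at least 0.313 with an estimated correlation). TGF-beta genes had 0.0728 with the scan batch as a block. Differences without 1 mouse (r) follow. Without Adamts5Dcat 1-week r1, TGF-beta (-0.29) lost the call. Without Adamts5Dcat 1-week r2, TGF-beta (-0.41) kept the call. Without Adamts5Dcat 1-week r3, TGF-beta (0.035) lost the call and collagens (-0.20) and ribosomal (0.20) kept it. Without Adamts5Dcat 1-week r4, cartilage (-0.12) lost the call. Without WT 1-week r1, TGF-beta (-0.10) lost the call and muscle (-1.71) kept it. Without WT 1-week r2, TGF-beta (-0.47), cartilage (-0.50) and neutrophil (1.70) kept the call. Without WT 1-week r3, TGF-beta (-0.21), cartilage (-0.033), cell cycle (0.21), muscle (-0.053) and neutrophil (-0.19) lost the call and collagens (-0.21), ribosomal (0.33) and hypoxia (-0.44) kept it. With median centring cartilage (-0.28, camera adjusted p = 0.244) and TGF-beta (-0.37, 0.102), and with processed signals TGF-beta (-0.32, camera adjusted p = 0.149) lost it. At 6 weeks they were neutrophil 1.65 (-0.80 and 4.09), macrophage 0.63 (-0.62 and 1.88) and erythroid markers 0.54 (-0.92 and 2.00), cell cycle 0.71 (-0.23 and 1.59), complement 0.49 (0.25 and 0.74), ribosomal protein 0.34 (0.51 and 0.17) and cartilage matrix genes 0.27 (0.37 and 0.17) (up to 0.0458; adjusted p at least 0.8 with an estimated correlation). With the arrays of 1 mouse exchanged, cartilage matrix genes were at 0.17 (camera adjusted p = 0.274) and ribosomal protein genes at 0.22. Without Adamts5Dcat 6-week r1, complement (0.55) and erythroid (0.52) lost the call. Without Adamts5Dcat 6-week r2, cartilage (0.25) and complement (0.37) lost the call. Without Adamts5Dcat 6-week r3, cartilage (0.26), complement (0.49), erythroid (0.32) and macrophage (0.42) lost the call and neutrophil (0.86) kept it. Without Adamts5Dcat 6-week r4, cartilage (0.22) lost the call. Without WT 6-week r1, cartilage (0.17) lost the call and erythroid (0.90) and macrophage (1.01) kept it. Without WT 6-week r2, cartilage (0.25) and ribosomal (0.16) lost the call and erythroid (0.91) kept it. Without WT 6-week r3, cartilage (0.25), complement (0.39), erythroid (0.16) and macrophage (0.49) lost the call. Without WT 6-week r4, cell cycle (0.30), complement (0.36), erythroid (0.18) and macrophage (0.086) lost the call and cartilage (0.41) and neutrophil (1.05) kept it. Cartilage also lost it without WT 1-week replicate 3 and WT 2-week replicate 4 (camera adjusted p up to 0.052). With median centring cartilage (0.18, camera adjusted p = 0.0613), and with processed signals cartilage (0.30, camera adjusted p = 0.0617), complement (0.52, 0.137) and macrophage (0.58, 0.0727) lost it.

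Some genes, picked for this, had one sign in all mice of a group and the opposite in all of another. Differences and chance were not tested. Between WT mice at 1 week and Adamts5Dcat mice at 6 weeks, the differences in log2(DMM/sham) were -1.08 for Bcorl1, -1.59 for Ltbp3, 1.29 for Cd177, 2.75 for Csf3r and -2.68 for Gpx3, in that order -0.55, -1.34, 1.22, 1.99 and -2.08 with the arrays of Adamts5Dcat 6-week replicate 4 exchanged and -1.02, -1.53, 1.35, 2.74 and -2.51 without that mouse. Between WT mice at 2 weeks and Adamts5Dcat mice at 6 weeks they were -1.30 for Ltbp3 and -1.92 for Gpx3 (-1.04 and -1.33 exchanged, -1.23 and -1.76 without it). The opposite signs held without that mouse for these genes and were lost for each with its arrays exchanged. Between WT mice at 6 weeks and Adamts5Dcat mice at 1 week the difference was 1.17 for Cox6a2, which that mouse does not enter.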

How the results depend on the processing

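The exchanged arrays, the fits within scan batches, the covariates for other tissues, batch as a block in the sham and list tests, and the mean of the 5 groups were chosen after seeing the data. The main counts were 5, 302, 116, 4 and 0 genes for DMM in WT mice at 1, 2 and 6 weeks and Adamts5Dcat mice at 1 and 6 weeks, 0 in each of 5 differences, and 1 and 2 in the sham. Over all alternatives 115 counts moved and 339, many of them 0 in both settings, stayed within 1.5 times. Of the named genes 8679 values kept direction and side of the threshold, 1100 kept direction but lost the call, 344 gained it and 30 turned. Of the called list means 1311 were the same, 266 lost the call and 28 turned (with an estimated correlation, fry, the blocks, the arrays exchanged, each scan batch alone and 1 mouse left out). Moved counts follow, the cause untested except where fewer mice, degrees of freedom or genes enter. Processed signals gave 3 in WT 1 week, 33 (19 up, 14 down) in WT 6 weeks and 1 in Adamts5Dcat 1 week. No background correction gave 1 in WT 1 week and 212 in WT 6 weeks. Median centring gave 78 (69 up, 9 down) in WT 2 weeks, 63 (59 up, 4 down) in WT 6 weeks and 1 in Adamts5Dcat 1 week. No filter on dim probes gave 198 in WT 2 weeks and 70 in WT 6 weeks. The mean over the probes of a gene gave 10 in WT 1 week, 58 in WT 6 weeks and 2 in Adamts5Dcat 1 week. Fits of only the groups compared gave 0 in WT 1 week, WT 6 weeks and Adamts5Dcat 1 week. Every array with the mouse as a random block gave 280 in WT 1 week, 1809 in WT 2 weeks, 1729 in WT 6 weeks, 155 in Adamts5Dcat 1 week, 1 in WT 6 minus 1 week and 1 in Adamts5Dcat 6 minus 1 week. Arrays with DMM in Cy5 only gave 9 in WT 1 week, 204 in WT 6 weeks, 29 in Adamts5Dcat 1 week and 8 in Adamts5Dcat 6 weeks. Array weights gave 2938 in WT 1 week, 1962 in WT 2 weeks, 2934 in WT 6 weeks, 493 in Adamts5Dcat 1 week, 8 in Adamts5Dcat 6 weeks and 1 in Adamts5Dcat 6 minus 1 week. The authors' value table gave 44 in WT 1 week, 936 in WT 2 weeks, 814 in WT 6 weeks, 40 in Adamts5Dcat 1 week and 148 in Adamts5Dcat 6 weeks. Trended and robust eBayes gave 0 in WT 1 week, WT 2 weeks, WT 6 weeks and Adamts5Dcat 1 week. A 2-fold minimum gave 621 in the mean of the 5 groups. Scan batch as a block gave 1 in WT 1 week. The exchanged arrays gave 44 in WT 1 week, 946 in WT 2 weeks, 817 in WT 6 weeks, 37 in Adamts5Dcat 1 week and 151 in Adamts5Dcat 6 weeks. Scan batch 1 alone gave 8 in WT 1 week, 50 in WT 2 weeks and 615 in WT 6 weeks. Scan batch 2 alone gave 0 in WT 1 week, WT 2 weeks, WT 6 weeks, Adamts5Dcat 1 week and the mean of the 5 groups. Covariates for other tissues gave 0 in WT 1 week, 0 in WT 2 weeks, 1 in WT 6 weeks and 0 in Adamts5Dcat 1 week.

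Leaving out 1 mouse (r for replicate) moved these counts. In WT 1 week the count ran from 0 to 38: 0 without WT 1-week r1, WT 2-week r2, WT 6-week r1 and Adamts5Dcat 6-week r3, 1 without WT 6-week r3 and Adamts5Dcat 6-week r2, 2 without WT 1-week r3 and WT 2-week r3, 3 without WT 1-week r2 and WT 2-week r4, 8 without WT 6-week r4, 38 without Adamts5Dcat 6-week r4. In WT 2 weeks the count ran from 0 to 857: 0 without WT 2-week r1, r2, r3 and r4, 111 without WT 1-week r1, 144 without Adamts5Dcat 6-week r3, 155 without Adamts5Dcat 1-week r2, 159 without WT 6-week r1, 180 without Adamts5Dcat 1-week r4, 190 without Adamts5Dcat 6-week r1, 623 without WT 6-week r4, 857 without Adamts5Dcat 6-week r4. In WT 6 weeks the count ran from 0 to 1823: 0 without WT 6-week r2 and r3, 1 without WT 6-week r1, 41 without WT 1-week r1, 44 without WT 2-week r2, 47 without Adamts5Dcat 6-week r1 and r3, 53 without WT 2-week r3 and Adamts5Dcat 1-week r2, 58 without WT 2-week r1, 73 without WT 1-week r2, 187 without Adamts5Dcat 1-week r1 and Adamts5Dcat 6-week r2, 713 without Adamts5Dcat 6-week r4, 1823 without WT 6-week r4. In Adamts5Dcat 1 week the count ran from 0 to 24: 0 without Adamts5Dcat 1-week r2 and r4, 1 without WT 1-week r2, WT 2-week r2, WT 6-week r2 and r3, Adamts5Dcat 1-week r1 and r3 and Adamts5Dcat 6-week r1 and r2, 2 without WT 6-week r1 and r4, 24 without Adamts5Dcat 6-week r4. In Adamts5Dcat 6 weeks the count ran from 0 to 13: 13 without Adamts5Dcat 6-week r4. In the 6-week sham it ran from 1 to 2, with 1 without WT or Adamts5Dcat 6-week r3. The 5 differences stayed at 0 and the 1-week sham at 1.

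The genes whose log2(DMM/sham) turned in sign under another setting had not passed the threshold, and the cause was not tested. Turned values were, with median centring Adamts5 in WT 6 week 0.17, with the mean over probes Adamts5 in WT 6 week 0.029, with DMM in Cy5 only Rps27 in WT 1 week 0.062, with array weights Adamts5 in WT 1 week -0.097, Adamts5 in Adamts5Dcat 1 week 0.18 and Adamts5 in Adamts5Dcat 6 week -0.18, in the authors' value table Adamts5 in Adamts5Dcat 6 week -0.36, with the arrays exchanged Adamts5 in Adamts5Dcat 6 week -0.36, with the covariates Adamts5 in WT 1 week -0.059. In scan batch 1 alone they were Kel in WT 6 week 0.41, Slc4a1 in WT 6 week 0.62, Mmp8 in WT 6 week 0.084, Retnlg in WT 6 week 0.91, Mpo in WT 6 week 0.68, H2-Aa in Adamts5Dcat 1 week 0.064, Adamts5 in WT 1 week -0.39 and Adamts5 in Adamts5Dcat 1 week 0.62. In scan batch 2 alone they were Ltf in WT 2 week -0.21, Cst6 in Adamts5Dcat 6 week -0.045, Mmp13 in WT 2 week -1.12, Mmp2 in WT 2 week -0.079 and Adamts5 in Adamts5Dcat 6 week -0.043.

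List means called over all mice also turned in a batch alone, with the cause not tested. The following are values in scan batch 1. In WT 1 week means were -0.081 for hypoxia genes, 0.021 for neutrophil markers and 0.12 for macrophage markers. In WT 2 week the mean was 0.0065 for muscle markers. In WT 6 week means were 0.22 for cell cycle genes, 0.44 for erythroid markers and 0.19 for neutrophil markers. In Adamts5Dcat 1 week the mean was -0.017 for ribosomal protein genes. In WT 6 week minus 1 week the mean was 0.11 for muscle markers. In Adamts5Dcat 6 week minus 1 week the mean was -0.16 for endoplasmic reticulum genes. In Adamts5Dcat minus WT at 1 week means were 0.020 for cartilage matrix genes, 0.066 for collagens, 0.065 for TGF-beta genes, -0.11 for cell cycle genes and -0.59 for neutrophil markers. In Adamts5Dcat minus WT at 6 week means were -0.23 for cell cycle genes, -0.92 for erythroid markers, -0.80 for neutrophil markers and -0.62 for macrophage markers. In scan batch 2, in WT 2 week minus 1 week the mean was -0.066 for immediate early genes. The lone WT 1-week mouse of that batch is assumed to vary like the other groups.

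With 1 mouse left out, values ranged and turned as follows, and the cause was not tested. Of genes, Adamts5, WT 1 week from -0.39 to 0.54, turned without WT 1-week r3 (-0.39); Mmp13, WT 2 week from -0.38 to 1.11, turned without WT 2-week r1 (-0.38) and WT 2-week r2 (-0.055); Mmp2, WT 2 week from -0.052 to 1.20, turned without WT 2-week r1 (-0.052); Adamts5, WT 6 week from -0.65 to 0.22, turned without WT 6-week r4 (0.22); Adamts5, Adamts5Dcat 1 week from -0.66 to 0.20, turned without Adamts5Dcat 1-week r3 (0.20); Adamts5, Adamts5Dcat 6 week from -0.24 to 0.28, turned without Adamts5Dcat 6-week r2 (-0.094) and Adamts5Dcat 6-week r4 (-0.24). Of lists, hypoxia genes, WT 1 week from -0.081 to 0.71, turned without WT 1-week r3 (-0.081); neutrophil markers, WT 1 week from -1.86 to 0.021, turned without WT 1-week r3 (0.021); macrophage markers, WT 1 week from -1.11 to 0.12, turned without WT 1-week r3 (0.12); hypoxia genes, WT 6 week minus 1 week from -0.77 to 0.029, turned without WT 1-week r3 (0.029). Further, muscle markers, WT 6 week minus 1 week from -1.53 to 0.13, turned without WT 1-week r3 (0.13); neutrophil markers, Adamts5Dcat minus WT, 1 week from -0.19 to 1.70, turned without WT 1-week r3 (-0.19); ribosomal protein genes, Adamts5Dcat 1 week from -0.033 to 0.47, turned without Adamts5Dcat 1-week r3 (-0.033); TGF-beta genes, Adamts5Dcat minus WT, 1 week from -0.47 to 0.035, turned without Adamts5Dcat 1-week r3 (0.035).

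With a replicate block the 5 differences stayed at 0 genes and the sham counts at 1 and 2. In the list tests the block lost oxidative phosphorylation genes in WT mice at 2 minus 1 week (camera adjusted p = 0.119) and TGF-beta genes between genotypes at 1 week (0.0727), and changed no other call but added 2 in the former. Outside WT mice at 1 and 6 weeks the numbers did not pair the mice, with r of deviations from -0.181 to 0.393. The panel has 37 measured genes, and 4 have no value (Adamts4, Il6 and Nos2 were dim and Prg4 had no probe by that name). Of 185 gene and group pairs 7 were called, 97 changed sign under at least 1 alternative, 42 were called under at least 1, and the 7 called kept their sign but were each lost under at least 1. The 24 pairs printed were picked after these values were seen, partly for length. Between 23.3% and 79.9% of a channel's spots were well above background. Median centring moved the median of all genes by 0.15, 0.18 and 0.16 in WT mice at 2 and 6 weeks and Adamts5Dcat mice at 6 weeks, and by 0.16, 0.18, 0.34 and -0.11 in the 3 time differences and between genotypes at 1 week, so its splits and list means are relative to that shift. It lost 17 of 67 list calls and turned 6 of their means.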

Other observations

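The tests in this part on the mean of the 5 groups were chosen after seeing the data. The split tests of the DMM counts in WT mice and in Adamts5Dcat mice at 1 week, of the sham and of that mean were written before their results were seen, and the other split tests after. Averaged over the 5 groups, DMM cartilage had higher RNA of Npy, a neuropeptide (3.07 (SE 0.57), up in 17 of 19 mice, limma adjusted p = 0.00177), Penk, the enkephalin precursor (2.75 (SE 0.51), 17 of 19), and Mgp, matrix Gla protein, which inhibits calcification (2.59 (SE 0.51), 16 of 19). It had lower RNA of Omd, the proteoglycan osteomodulin (-2.94 (SE 0.60), down in 16 of 19), Adamtsl2 (-2.19 (SE 0.24), 18 of 19, adjusted p = 9.28e-05) and Galnt16 (-2.18 (SE 0.32), 18 of 19). Phlda2 (3.05 (SE 0.29)) and Inhba (3.00 (SE 0.28)) were up in 18 of 19 mice. With the arrays of Adamts5Dcat 6-week replicate 4 exchanged these shares were 18 for Npy and Penk, 17 for Mgp, 17 for Omd, and 19 for Adamtsl2, Galnt16, Phlda2 and Inhba.

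In that average 2631 genes were up and 2886 down (2848 and 873 with median centring), and 377 and 244 were at least 2-fold. Of all called, 294 and 248 had the same sign in at least 18 of 19 mice as recorded, 534 and 539 with the arrays of 1 mouse exchanged, and 648 and 621 in at least 17 of 18 without that mouse. In all, 5033 were called both as recorded and exchanged. Of the immediate early and heat shock list, 18 of 36 were up and 1 down (19 and 2 adjusted over the list alone; mean 0.60, camera adjusted p = 8.77e-07, fry adjusted p = 0.00407, and adjusted p = 0.594 with an estimated correlation). Of the TGF-beta list 13 of 32 were up and 2 down (14 and 2 adjusted over the list alone; mean 0.55, 0.000857 and 0.00407, and adjusted p = 0.594 with an estimated correlation). Oxidative phosphorylation (14 of 38 up and 4 down, 16 and 6 adjusted over the list alone; mean 0.23, camera adjusted p = 0.00864, fry adjusted p = 0.104) and oxidative stress genes (10 of 34 up and 1 down, 11 and 1 adjusted over the list alone; 0.23, 0.0326 and 0.104) were called by camera. These too were lost with an estimated correlation (adjusted p = 0.842). Of the BMP list 11 of 32 were up and 6 down (11 and 7 adjusted over the list alone), with a list mean above 0 in 18 of 19 mice as recorded and 17 with the arrays of 1 mouse exchanged (fry adjusted p = 0.00542, camera adjusted p = 0.274, and adjusted p = 0.594 with an estimated correlation). The count stayed between 4164 and 6287 with 1 mouse left out, was 5619 with scan batch as a block and 4582 within batch 1, and was 0 within batch 2. Of 100 splits with the signs of mice turned at random, 1 gave as many genes, the real one. The highest other gave 1314, so chance signs are argued against.

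For the DMM counts in single groups the splits are too few for a share under 0.05. Of 4 splits in WT mice at 1 week 1 gave as many, the real one (5 genes, highest other 0), of 8 in WT mice at 2 weeks 1 (302, highest other 0), of 8 in WT mice at 6 weeks 2 (116, highest other 617), and of 8 in Adamts5Dcat mice at 1 week 1 (4, highest other 0). In Adamts5Dcat mice at 6 weeks 8 of 8 gave at least the real count of 0, with 149 as the highest other. The split with 617 turned WT 6-week replicate 4 and that with 149 turned Adamts5Dcat 6-week replicate 4, which points to a structure of these samples. A count of 0 is reached by every split, so for the differences, with 35 of 35 splits each, the test says nothing about them. Their highest other counts were 19 and 2 genes for WT 2 and 6 weeks minus 1 week, in splits that follow the scan batch, 21 for Adamts5Dcat 6 weeks minus 1 week, 1 between genotypes at 1 week and 0 at 6 weeks.

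For the sham probes, only the real split of 35 gave as many at 1 week (1, highest other 0), weakly against chance. At 6 weeks 4 of 35 gave 2 or more, so chance is not excluded, and the highest other, 22, follows the scan batch, with 2 probes called when the batch is a block. NAP018089-001 was also apart in the DMM leg, where the lowest Adamts5Dcat mouse had a log2 level of 7.77 and the highest WT mouse 7.67. NAP056910-1 was apart in the sham at 6 weeks and not at 1 week, when the 4 Adamts5Dcat mice lay within the WT range.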
